A study of Mus musculus with 91 samples.

How the data were processed

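The deposited values were counts, raw reads per gene in 8 tables, which the authors made, per the submitters' processing notes, by aligning reads to the mouse genome GRCm38 with STAR 2.5.0 and counting Ensembl genes of GENCODE M13 with featureCounts 1.5.0. RNA was purified from sorted cells with TRIzol and a column, ribosomal RNA was removed, and total RNA libraries were read on a NextSeq 500, so that RNA without a poly(A) tail, such as that of replication-dependent histone genes, was measured too. The authors had removed genes with low counts: every gene kept had over 0.5 CPM, counts scaled to the library total, in at least 3 columns of its table, checked on the values. Whether counting used the strand of the reads is not stated, so values of genes that overlap another gene on the opposite strand are uncertain. Reads shared between closely related genes (histone, granzyme and globin genes, ribosomal protein genes and their pseudogenes) can fall to either member.

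Samples were grouped by the treatment in their labels. The 91 samples held 75 libraries. In the 72 h and in vitro tables every library had been run on the sequencer a second time, giving 16 further samples, and both runs were summed. The chi-square per degree of freedom between the runs of a library was 1.03 to 1.08, against 1.89 to 68.7 between a library and another replicate of its group, over genes with a summed count of at least 20. In the 4 h table the labels of 2 libraries contradict each other: title, treatment label and column name agree, and the injected molecule names another treatment. These 2 were left out of every comparison except in 1 alternative. The treatment text is the same for every sample, naming 20 µg of FP and 1.5 h, so the time was taken from the treatment label. The labels do not state that replicates are separate animals, so p-values measure only the spread between these samples.

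Each table was fitted on its own with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM scaling, the filterByExpr low-count filter, one mean per group and a quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene counted as changed below 0.01, the threshold the authors name. These tests are 2-sided. Standard errors (SE) of log2 changes were the absolute change divided by the square root of F. The intervals called 95% take a normal multiplier of the SE and ignore the few degrees of freedom of the F test. They are therefore too narrow: Cish at 168 h had -0.375 to -0.00214, which leaves out 0, with an unadjusted F test p of 0.073. Levels are CPM scaled with TMM, as mean ± SD over the libraries of a group. The genes tested numbered 16643 (1.5 h), 17636 (4 h), 17453 (16 h), 18624 (72 h), 17411 (168 h), 16629 (in vitro), 16668 (high dose) and 17953 (restimulation), and the common biological variation was 16.3%, 38.4%, 11.2%, 16.0%, 19.9%, 4.48%, 40.7% and 27.0% in the same order. Whether an effect differed between tables was tested as an interaction, the difference of the log2 changes, with each table keeping its own PBS libraries. Overlaps of called genes were set beside the product of both counts over the genes tested in both tables, with a one-sided hypergeometric p, although genes are not independent replicates.

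The 23 gene lists were tested with camera (preset correlation 0.01, prior count 2), against all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison and a threshold of 0.05. They held IL-2 receptor and STAT5 targets, Treg core, effector Treg, resting or central T cell, conventional helper T cell, cell cycle, replication-dependent histone, ribosome biogenesis, ribosomal protein, glycolysis, cholesterol synthesis, amino acid supply and ATF4, oxidative phosphorylation, mitochondrially encoded, interferon-stimulated, immediate early and handling stress, chemokine receptor and homing, BCL2 family and chromatin regulator genes, and markers of B cells, myeloid cells, CD8 T and NK cells, and erythroid cells and platelets. Of the list results, 200 passed with the preset correlation and 13 with a correlation estimated from the data. These 13 were ribosome biogenesis, IL-2 receptor and STAT5, and Treg core genes in the 3 comparisons at 1.5 h, amino acid supply genes between FP and IL-2 at 1.5 h, Treg core and interferon-stimulated genes in vitro, and myeloid markers at 168 h.

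Named genes were taken by a rule: among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted and unnamed genes, the 8 with the largest increase and the 8 with the largest decrease (5 and 5 for FP against IL-2, in vitro, high dose and repeated FP against PBS), up to 4 members with the smallest p of each list past its test, and a panel of 22 genes of IL-2 signalling and Treg state. For the interactions the 5 largest differences in each direction and the panel were taken. Groups, tests, thresholds, lists, this rule and most alternatives were fixed before the data were examined. Some genes that the rules pick are not reported here. Positions are those of GENCODE M21 on GRCm38.

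The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors (RLE) in place of TMM, no further low-count filter, the replicate number as a block, leaving out each library in turn, only the compared groups in a fit, either run alone, the lane named in the sample identifiers (4 h), and the estimated correlation for lists. Added after seeing the data were the 2 libraries of contradicting labels grouped by title, the tag in the 4 h column names as a factor, the share of counts in genes of the TEC class, a class of unproven genes in GENCODE, as a covariate in the 4 h, high-dose and restimulation tables, and, for repeated FP against PBS, a fit without library 1 of the single injection in the shared spread. Replicate numbers were checked as pairs by correlating, across genes, the deviations of libraries from their group means. Only the numbers of 4 h FP and PBS (0.18 to 0.82), 4 h IL-2 and PBS (0.38 to 0.80) and 72 h IL-2 and PBS (0.29 to 0.42) all passed 0.1.

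Recovery was tested on simulated data with the spread of each table, 200 genes being changed by 1.5-fold, 2-fold or 4-fold. The comparison simulated was IL-2 against PBS, except FP against PBS at 168 h and single FP against PBS in restimulation. With only 200 changed genes the adjusted threshold is stricter than where many genes change. The shares can thus be too low for such comparisons and do not hold for every comparison of a table. At 4-fold, 96.9% of the changed genes were called at 1.5 h, 28.8% at 4 h, 96.9% at 16 h, 75.0% at 72 h, 73.4% at 168 h, 98.4% in vitro, 0% in the high-dose table and 45.5% in the restimulation table. At 2-fold the shares were 56.9%, 0%, 81.8%, 52.2%, 51.6%, 86.4%, 0% and 10.4% in the same order, with at most 4 false calls in a table. Genes were drawn independently, without any structure shared by the libraries. The false calls therefore do not cover such structure, which other splits of the real libraries show (up to 4005 genes at 4 h and 1473 in restimulation).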

Results

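Regulatory T cells (Tregs), the CD4 T cells that depend on the transcription factor Foxp3 and restrain other immune cells, were sorted from mouse spleen and their total RNA was sequenced. The animals, C57/BL6 mice with a red fluorescent Foxp3 reporter per the labels, had received mouse IL-2, a fusion protein of IL-2 with the receptor chain CD25 (FP), or PBS. At 1.5 h and 16 h there were 4 libraries each of PBS, IL-2 and FP. At 4 h there were 3 of PBS, 4 of IL-2 and 3 of FP, at 72 h 3 of PBS, 3 of IL-2 and 4 of FP, and at 168 h 3 of PBS and 4 of FP. An in vitro table (PBS or IL-2, 1.5 h) and a high-dose table (PBS or IL-2, dose and time not in the labels) held 3 libraries per group. A restimulation table (1.5 h) held 3 libraries after PBS and a second PBS, 3 after PBS and then FP (single injection), and 4 after FP and a second FP. Library totals were 12.2 to 15.3 M reads at 1.5 h, 14.5 to 24.3 at 4 h, 13.9 to 17.6 at 16 h, 20.6 to 27.8 at 72 h, 17.2 to 43.5 at 168 h, 19.5 to 24.8 in vitro, 18.7 to 31.5 at high dose and 29.0 to 46.1 in restimulation. Each table had PBS libraries of its own, and every change below is against these unless another group is named.

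What IL-2 alone does first was asked at 1.5 h (n = 4 and 4). Lif, a cytokine of the IL-6 family (ENSMUSG00000034394, chromosome 11, 4257557 to 4272514), rose by a log2 change of 3.96 ± 0.23 (SE), from 4.76 ± 0.681 to 73.9 ± 11.7 CPM, with an adjusted p of 1e-07. Il2ra, which encodes CD25, the high-affinity subunit of the IL-2 receptor (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), rose by 1.88 ± 0.088, from 597 ± 40 to 2190 ± 135 CPM. Feedback inhibitors of JAK-STAT signalling rose with it, Socs2 (ENSMUSG00000020027, chromosome 10, 95385362 to 95417180) by 2.21 ± 0.12, Socs1 by 2.03 ± 0.085 and Cish by 1.90 ± 0.12. The actin regulator Enah, the potassium channels Kcnj15 and Kcnk5, the growth factor Hbegf, the transcription factor Myb and the cytokine gene Lta rose by 3.76, 3.27, 3.11, 3.19, 3.01 and 2.99. Lrrc32, whose protein holds latent TGF-beta on Tregs, rose by 2.21 ± 0.12 and Foxp3 itself by 0.83 ± 0.088. Arl5c fell by 2.08 ± 0.13, the pro-apoptotic Bbc3 by 1.76 ± 0.22 (22 ± 6.8 to 6.5 ± 1.45 CPM), the IL-7 receptor gene Il7r by 1.62 ± 0.18 (417 ± 85.0 to 135 ± 26.6 CPM) and Tcf7, a transcription factor of resting T cells, by 1.51 ± 0.10. In all, edgeR called 2360 genes, 1397 higher and 963 lower, of which 633 changed at least 2-fold.

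Ribosome biogenesis genes moved as a block at 1.5 h of IL-2: all 34 measured were called higher (34 adjusted over the list alone), with a median log2 change of 1.2 and an adjusted camera p of 1.3e-35. Tsr1, Nop2 and Noc4l, which act in ribosome assembly, rose by 1.38, 1.37 and 1.39. Of 26 IL-2 receptor and STAT5 targets 14 were higher, 1 lower and 11 not past (17 higher and 1 lower adjusted over the list alone), with an adjusted camera p of 1e-11, and of 18 Treg core genes 7 were higher and 11 not past (9 higher adjusted over the list alone, p 2e-05). Amino acid supply and ATF4 genes had 11 of 19 higher and 1 lower (11 and 1 adjusted over the list alone, p 4e-06), with the transporter Slc7a5 up by 1.88 ± 0.13 and the ATF4 target Trib3 by 2.91 ± 0.24. Cholesterol synthesis genes had 8 of 22 higher (10 higher and 1 lower adjusted over the list alone, p 0.0020) and interferon-stimulated genes 6 of 31 higher (8 adjusted over the list alone, p 0.00029). Glycolysis genes had 6 of 17 higher and 2 lower (p 0.018), with Hk2, a hexokinase, up by 1.73 and the glucose transporter Slc2a3 down by 0.93. Resting or central T cell genes had 2 of 20 higher and 6 lower (2 and 7 adjusted over the list alone, p 0.0024). Chemokine receptor and homing genes had 1 of 25 higher and 5 lower (p 0.018), with Ccr7 down by 0.73 and Itga4, an integrin chain, down by 0.77. With an estimated correlation the adjusted p was 0.038 for ribosome biogenesis, 0.0071 for STAT5 targets and 0.021 for Treg core genes, and 0.085 to 0.64 for the other lists named here, which lost their call.

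The question for FP at 1.5 h (n = 4 and 4) was whether the fusion starts the response of IL-2. Lif rose by 3.15 ± 0.23 to 42.3 ± 14.9 CPM, Il2ra by 1.79 ± 0.088 to 2060 ± 150 CPM, Socs2 by 2.13 ± 0.12 to 110 ± 5.88 CPM, Lta by 2.75 ± 0.12 and Myb by 2.69 ± 0.17. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) rose by 0.73 ± 0.088, from 483 ± 36.7 to 803 ± 38.4 CPM. Il7r fell by 1.47 ± 0.18, Bbc3 by 1.52, Tcf7 by 1.07 and the PI3K inhibitor gene Pik3ip1 by 1.56. Of 34 ribosome biogenesis genes 28 were higher (33 adjusted over the list alone), with an adjusted camera p of 9.5e-37, and of 26 STAT5 targets 13 were higher and 1 lower (15 and 1 adjusted over the list alone, p 1.4e-12). Both kept the call with an estimated correlation, at an adjusted p of 0.035 and 0.0054. edgeR called 1110 genes, 730 higher and 380 lower, and DESeq2 called 1700 (1030 and 670). Without FP library 1, FP library 3 or PBS library 1 the count fell to 699, 689 or 737.

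Set against IL-2 at 1.5 h, FP differed in no gene by edgeR, with 970 genes at an unadjusted p below 0.05 and 1 gene called by DESeq2. Lif was lower after FP by 0.81 ± 0.20 (adjusted p 0.62), Slc7a5 lower by 0.58 ± 0.12 and Tcf7 higher by 0.45 ± 0.10, all uncalled. Il2ra differed by -0.0864 (95% interval -0.253 to 0.0805) and Socs2 by -0.0769 (-0.29 to 0.137). Ribosome biogenesis genes, none of which was past the test alone or adjusted over the list alone, were lower after FP than after IL-2 with a median of -0.30, an adjusted camera p of 8.4e-35 and an adjusted p of 0.046 with an estimated correlation. Amino acid supply genes (median -0.22, 1 lower adjusted over the list alone) had a p of 3.4e-09, also 0.046 with an estimated correlation. STAT5 targets (median -0.16, p 7.2e-05) and Treg core genes (median -0.14, p 0.0011) had no member past either test, and 0.046 each with an estimated correlation.

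**Figure D1:**
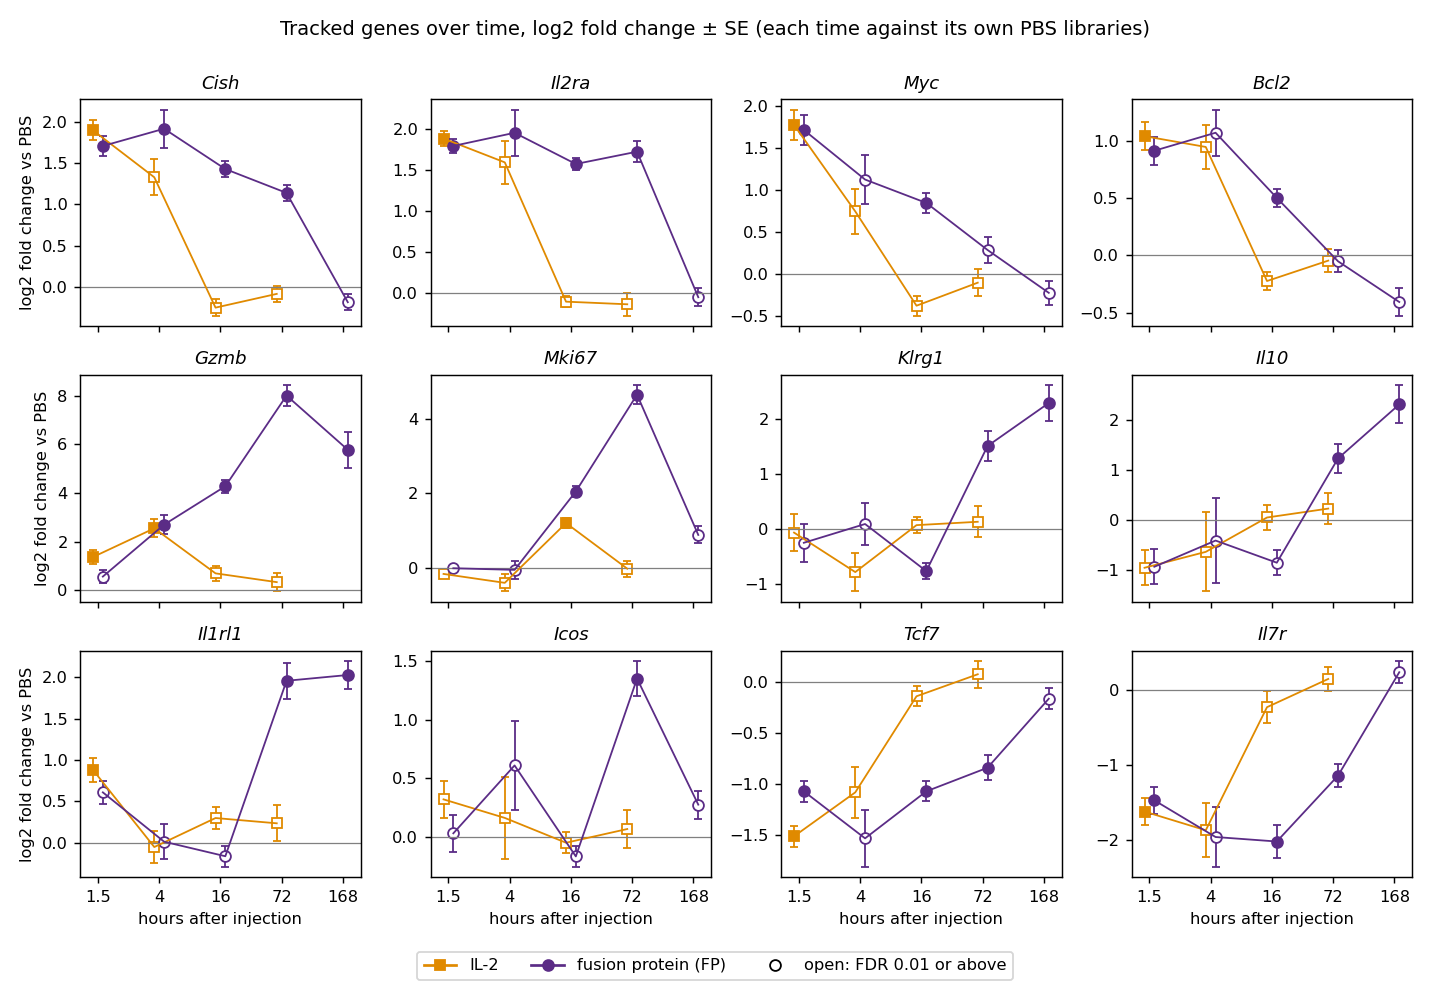
Log2 change ± SE of 12 tracked genes after IL-2 and FP from 1.5 h to 168 h, each time against its own PBS libraries. Open marks are changes that were not called.

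Genes of growth stayed high at 4 h, where IL-2 (n = 4) and FP (n = 3) were set against PBS (n = 3) to see how long the first response lasts. Enah rose by 5.13 ± 0.48 after IL-2 and 4.86 ± 0.49 after FP, Slc1a4, a neutral amino acid transporter, by 3.8 ± 0.35 and 3.64 ± 0.36, and Slc7a5 by 2.47 ± 0.21 and 2.26 ± 0.22. Lif rose from 5.46 ± 2.01 CPM to 56.2 ± 10.9 CPM after IL-2 and 82.3 ± 7.03 CPM after FP. Gzmb, the gene of granzyme B, a serine protease of cytotoxic granules (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), rose by 2.55 ± 0.37 after IL-2, from 3.23 ± 0.749 to 18.9 ± 4.12 CPM, and by 2.70 ± 0.39 after FP. Il2ra rose by 1.95 ± 0.28 after FP (adjusted p 0.0056), while after IL-2 its change of 1.59 ± 0.26 was not called (0.013). Abca1, a cholesterol exporter, fell by 1.78 after IL-2, and the sialyltransferase gene St8sia6 fell by 1.59 and 1.69. By edgeR 115 genes changed after IL-2 (100 higher, 15 lower) and 161 after FP (127 higher, 34 lower), against 790 and 1100 by DESeq2. With replicate numbers as a block the counts were 509 (417 and 92) and 994 (693 and 301). All correlations between libraries of the same number passed 0.1. Yet FP library 2 went with PBS library 1 (0.614), with which it shares a tag in the column names, more than with PBS library 2 (0.18). IL-2 library 3 went with PBS library 4 (0.759) nearly as much as IL-2 library 4 did (0.798). The numbers are thus not shown to be pairs for FP or for IL-2. With the tag as a factor, added after seeing the data, the FP count was 1684. A fit of only the compared groups gave 27 and 0, and the lane as a covariate 47 and 0. With the 2 libraries of contradicting labels grouped by their titles, added after seeing the data, the counts were 379 and 596, with all 115 and 161 genes among them. Leaving out a library lowered the counts, for IL-2 to 23, 26 and 56 without IL-2 libraries 2, 3 and 4, and to 10, 1 and 14 without PBS libraries 1, 2 and 4. For FP the counts were 36, 27 and 89 without FP libraries 1, 2 and 4, and 29, 10 and 31 without PBS libraries 1, 2 and 4.

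Lists of growth and supply were raised at 4 h by either protein. Ribosome biogenesis genes were higher in 9 of 34 after IL-2 (28 adjusted over the list alone, median 1.3, adjusted camera p 6e-35) and in 9 after FP (31 adjusted over the list alone, median 1.4, p 1.2e-30). Amino acid supply genes were higher in 5 of 20 after either protein (12 and 13 adjusted over the list alone, p 1.3e-15 and 5.2e-13). STAT5 targets were higher in 4 of 26 after IL-2 and 8 after FP (12 higher and 1 lower, and 11 and 1, adjusted over the list alone; p 2.5e-09 and 3.1e-11). Cholesterol synthesis genes had no member past the test over all genes, yet 7 and 8 higher adjusted over the list alone (p 3.8e-08 and 1.8e-09). The 7 mitochondrially encoded genes had a median of 0.67 after FP (p 0.0025, no member past). None of these kept its call with an estimated correlation, where the adjusted p was 0.24 to 0.89 over the lists at 4 h. Between FP and IL-2 edgeR called 0 genes, DESeq2 called 4, and 482 had an unadjusted p below 0.05. Lta was higher after FP by 0.87 ± 0.22 (adjusted p 0.95), replication-dependent histone genes had a median of 0.95 (adjusted camera p 1.2e-14), ribosomal protein genes of 0.60 (3.2e-13) and chromatin regulators of -0.18 (0.00044), with no member past the test and an adjusted p of 0.71 to 0.89 with an estimated correlation.

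By 16 h the proteins had parted, and the question was which arm still signalled. After IL-2 (n = 4 and 4) the proliferation marker Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) rose by 1.20 ± 0.14, from 42.1 ± 3.84 to 96.8 ± 23.4 CPM, with an adjusted p of 0.00063. The kinetochore gene Kntc1 rose by 1.58 ± 0.15, Top2a, a topoisomerase of dividing cells, by 1.19 ± 0.14 and histone gene Hist1h3c by 1.82 ± 0.26. Il2ra differed from PBS by -0.106 (95% interval -0.245 to 0.0335) and Socs2 by -0.0872, both uncalled. edgeR called 61 genes, 60 of them higher, and DESeq2 137 (106 and 31), and a fit of only the compared groups called 7. Of 41 cell cycle genes 14 were higher (24 adjusted over the list alone, median 0.60, adjusted camera p 4.1e-37), and of 51 histone genes 8 (28 higher and 1 lower adjusted over the list alone, p 4.1e-25). Ribosome biogenesis genes had turned to a median of -0.34 with no member past (16 lower adjusted over the list alone, p 9.3e-24). With an estimated correlation no list kept its call (adjusted p 0.055 to 0.70). The count fell to 22 and 19 without IL-2 libraries 2 and 3, and to 37 and 35 without PBS libraries 2 and 4.

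FP at 16 h (n = 4 and 4) kept the early genes up and added DNA replication. Il2ra stood at 1960 ± 87.7 CPM against 657 ± 42.5 (log2 change 1.57 ± 0.073), Socs2 rose by 2.31 ± 0.091, Lif by 3.51 ± 0.16, Lrrc32 by 2.04 and Enah by 5.19 ± 0.22. Mcm10 and Cdc6, which load and start replication origins, rose by 5.11 ± 0.19 and 4.20 ± 0.12, the checkpoint kinase gene Chek1 by 3.70 and Mki67 by 2.05 ± 0.14. Gzmb rose by 4.28 ± 0.27, from 4.20 ± 2.45 to 82.4 ± 10.8 CPM (adjusted p 4.1e-09). Bcl6, a transcriptional repressor of follicular T cells, fell by 2.2 ± 0.12 (41.7 ± 7.48 to 9.10 ± 1.12 CPM), Il7r by 2.02 ± 0.22, Tcf7 by 1.07 and Klrg1, an inhibitory receptor, by 0.76 ± 0.14. edgeR called 5022 genes, 2519 higher and 2503 lower, 1202 of them at least 2-fold. Against IL-2 at 16 h (n = 4 and 4) it called 5544 (2940 and 2604), with Enah higher by 5.60 ± 0.23, Gzmb by 3.59 ± 0.26, Socs2 by 2.40 and Il2ra by 1.68 ± 0.073, and with Bcl6 and Il7r lower by 2.27 and 1.80.

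Division and metabolism lists rose together after FP at 16 h. Cell cycle genes were higher in 40 of 41 (41 adjusted over the list alone, median 1.9, adjusted camera p 8.8e-34) and ribosome biogenesis genes in 33 of 34 (median 0.89, p 1.7e-20). Oxidative phosphorylation genes were higher in 21 of 30 (24 adjusted over the list alone, p 1.7e-09), glycolysis genes in 13 of 17 with 1 lower (p 2.4e-07), and cholesterol synthesis genes in 12 of 22 (13 adjusted over the list alone, p 5.5e-06). STAT5 targets were higher in 17 of 26 and lower in 2 (18 and 4 adjusted over the list alone, p 1.1e-07). Resting or central T cell genes were lower in 14 of 20 and higher in 3 (p 8.5e-05), chemokine receptor and homing genes lower in 14 of 26 and higher in 2 (p 0.00055), and effector Treg genes lower in 9 of 29 and higher in 2 (10 and 3 adjusted over the list alone, p 0.036). B cell markers were lower in 4 of 12 (5 adjusted over the list alone, p 0.0080) and myeloid markers in 1 of 14 (0 adjusted over the list alone, p 0.036). Against IL-2, 34 of 34 ribosome biogenesis genes were higher (median 1.1, p 2e-25), as were 31 of 41 cell cycle genes (32 adjusted over the list alone, p 1.4e-20), and effector Treg genes were lower in 15 and higher in 3 (p 0.0037). All of these lost their call with an estimated correlation, at an adjusted p of 0.074 to 0.85 against PBS and 0.19 to 0.56 against IL-2.

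**Figure D2:**
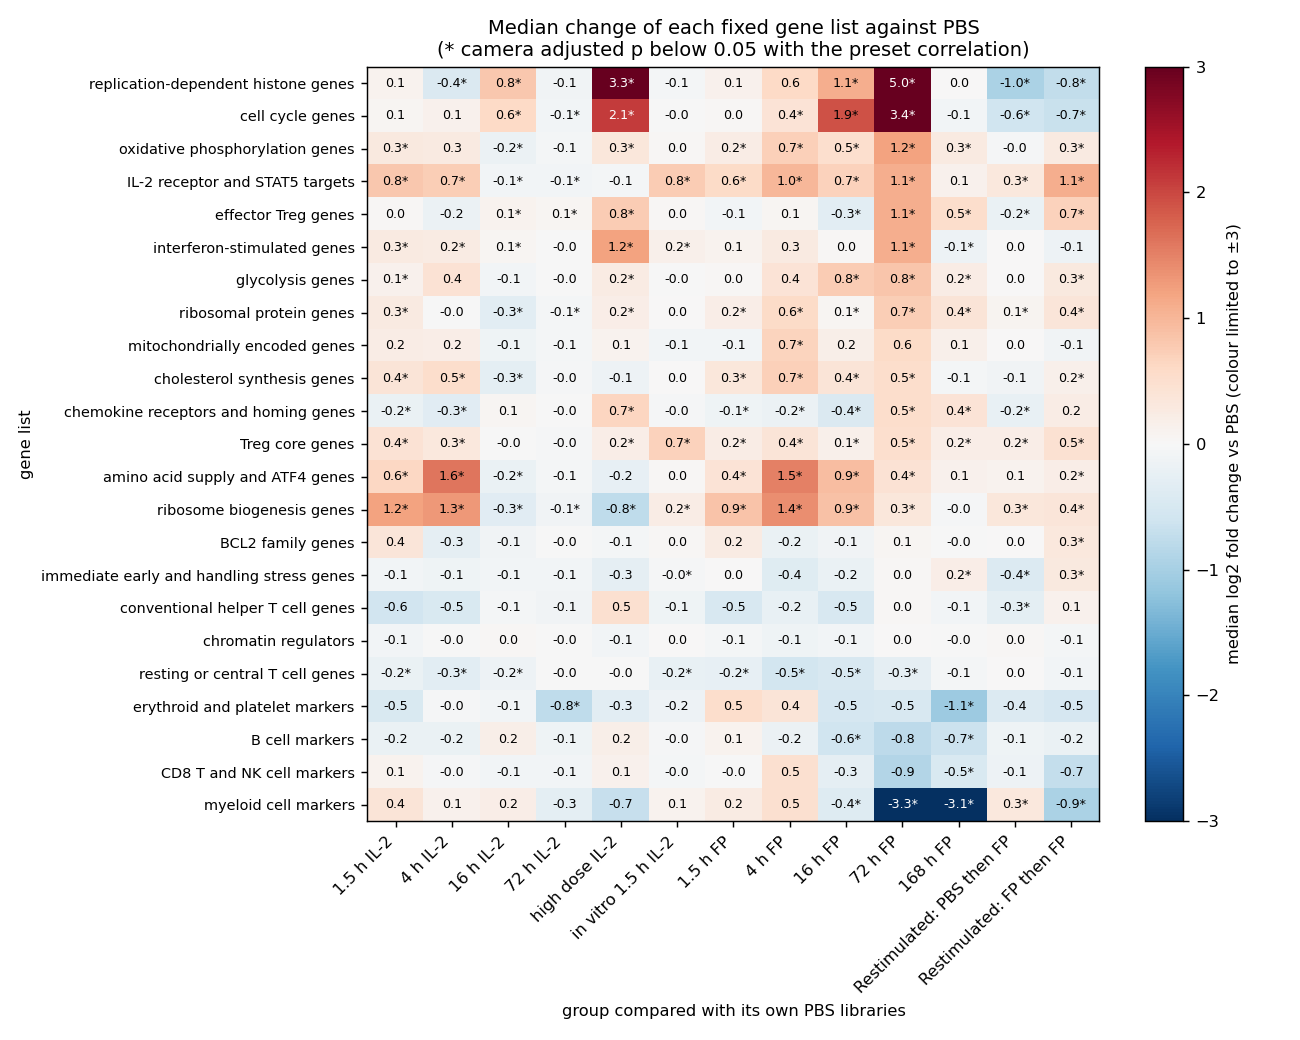
Median log2 change of each gene list against the PBS libraries of its table, with a star for lists past the camera test with the preset correlation.

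At 72 h IL-2 had left no called gene (n = 3 and 3): edgeR and DESeq2 each called 0, and 82 genes had an unadjusted p below 0.05. Il2ra differed from PBS by -0.138 (95% interval -0.407 to 0.13), Socs2 by -0.203 (-0.429 to 0.0225), Gzmb by 0.336 (-0.415 to 1.09) and Mki67 by -0.0292 (-0.469 to 0.41). Erythroid and platelet markers, among them the haemoglobin gene Hbb-bs at -1.19 ± 0.57, had a median of -0.77 with no member past the test (adjusted camera p 2.2e-08). Ribosome biogenesis genes had a median of -0.11 with no member past (p 5.1e-08). With replicate numbers as a block, which paired these libraries, still 0 genes were called, and 7 further lists gained a call, 6 lower, among them oxidative phosphorylation (0.00018), histone (0.0036) and immediate early genes (0.0054) and myeloid markers (0.013), and 1 higher, chemokine receptor and homing genes (0.045). Without the block, an estimated correlation gave the lists past the test an adjusted p of 0.19 to 0.95. Changes within these intervals cannot be ruled out, nor can somewhat larger ones, since the intervals are too narrow.

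Whether FP still acted at 72 h was asked with 4 FP and 3 PBS libraries. Gzmb rose by 8.01 ± 0.42, from 3.17 ± 1.89 to 813 ± 158 CPM (adjusted p 6e-08), and Gzma, another granule protease gene (ENSMUSG00000023132), by 8.48 ± 0.65, from 0.0747 ± 0.0938 to 30.7 ± 13 CPM. Ifitm1, an interferon-induced membrane protein gene, rose by 7.00 ± 0.35, Birc5, which encodes survivin, by 5.52 ± 0.23, Mki67 by 4.66 ± 0.25 and the calcium-binding S100a6 by 3.87 ± 0.31. Il2ra (1.72 ± 0.13) and Socs2 (2.55 ± 0.12) were still up, Klrg1 rose by 1.51, Il10, the gene of a suppressive cytokine, by 1.23 and Ctla4, an inhibitory receptor gene, by 1.00. Foxp3 differed by 0.18 (95% interval -0.00659 to 0.366). Genes of red pulp and other macrophages fell: the scavenger receptor gene Cd163 by 5.31 ± 0.50 (36.8 ± 17.1 to 0.948 ± 0.795 CPM), the iron exporter gene Slc40a1 by 5.11 ± 0.55, Mertk, a receptor for dying cells, by 5.30 ± 0.49, and Csf1r, the receptor for a macrophage growth factor, by 3.89 ± 0.47. edgeR called 5662 genes (3230 higher, 2432 lower), 2692 of them at least 2-fold, and 5738 against IL-2 (n = 3), where Gzmb was higher by 7.68 ± 0.41, Gzma by 7.52, Socs2 by 2.76 and Il2ra by 1.86. Without PBS library 2 or 3 the count against PBS was 3695 or 3549, and without IL-2 library 2 or 3 the count against IL-2 was 3762 or 3727.

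Histone genes led the lists after FP at 72 h, with 49 of 52 higher, a median of 5.0 and an adjusted camera p of 1.5e-27, though their sequences are close enough to share reads. Cell cycle genes were higher in 41 of 41 (median 3.4, p 6.5e-34), interferon-stimulated genes in 26 of 31 (28 adjusted over the list alone, median 1.1, p 5.2e-15) and oxidative phosphorylation genes in 29 of 30 (median 1.2, p 1.2e-10). Oas3, an antiviral enzyme gene, rose by 2.54 ± 0.11 and Gbp2, an interferon-induced GTPase gene, by 2.21. Effector Treg genes were higher in 21 of 29 and lower in 2 (21 and 4 adjusted over the list alone, p 3.5e-06), and STAT5 targets higher in 19 of 26 and lower in 2 (p 4.4e-08). Glycolysis genes were higher in 13 of 17 (p 1.9e-07), Treg core genes in 10 of 18 with 1 lower (p 0.00091), and chemokine receptor and homing genes in 10 of 27 with 3 lower (12 and 3 adjusted over the list alone, p 0.029). Myeloid markers were lower in 13 of 15 (median -3.3, p 2.3e-06), and resting or central T cell genes in 7 of 20 with 1 higher (8 and 1 adjusted over the list alone, p 0.0080). Every one of these calls was lost with an estimated correlation (adjusted p 0.19 to 0.70).

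What remained a week after FP was asked at 168 h (n = 4 and 3). Gzmb was higher by 5.78 ± 0.74, at 87.1 ± 72.1 against 1.42 ± 1.42 CPM (adjusted p 0.0014). FP library 1 had 195 CPM and the others 46.5 to 56.8, and without it the change was 5.03 ± 0.47, while without PBS library 2 or 3 the call was lost (adjusted p 0.011 each). Il10 rose by 2.31 ± 0.38, Klrg1 by 2.29 ± 0.32 (23.5 ± 8.01 to 115 ± 47.1 CPM), Il1rl1, the IL-33 receptor gene, by 2.03 ± 0.17 and Ccr2, a receptor for inflammatory chemokines, by 2.27 ± 0.33. Il2ra differed by -0.0522 (95% interval -0.276 to 0.171) and Mki67 by 0.88 ± 0.23 without being called. Spic, the transcription factor gene of red pulp macrophages, fell by 4.22 ± 0.34, Slc40a1 by 4.42 ± 0.29 (119 ± 8.72 to 5.60 ± 2.61 CPM) and the complement gene C1qa by 3.69 ± 0.23. edgeR called 210 genes, 35 higher and 175 lower, and DESeq2 520 (184 and 336). Myeloid markers were lower in 8 of 13 (12 adjusted over the list alone, median -3.1, adjusted camera p 1.9e-21) and kept the call with an estimated correlation (adjusted p 0.022). Effector Treg genes were higher in 5 of 29 (10 higher and 1 lower adjusted over the list alone, p 3.1e-11), CD8 T and NK cell markers lower in 2 of 9 (1 higher and 2 lower adjusted over the list alone, p 0.033), immediate early and handling stress genes higher in 1 of 23 (2 adjusted over the list alone, p 4e-04) and B cell markers shifted by -0.65 with no member past (1 lower adjusted over the list alone, p 0.00041), all lost with an estimated correlation (adjusted p 0.39 to 0.91). The 2 lower CD8 T and NK cell markers were Fcer1g (-3.03 ± 0.33) and Tyrobp (-1.71 ± 0.24), which are also on the macrophage list used further below. Nkg7 differed by 1.46 ± 0.34 and Eomes by -0.958 ± 0.35, both uncalled. A loss of CD8 T or NK cell RNA is thus not shown. The edgeR count fell to 135 and 139 without FP libraries 2 and 4, and to 128 without PBS library 1.

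Which genes FP moved differently at 72 h and 1.5 h was tested as an interaction, and edgeR called 2581 genes (1499 higher, 1082 lower at 72 h). Gzmb showed a difference of 7.46 ± 0.44 (adjusted p 1.6e-08), Mki67 of 4.69 ± 0.26, Il10 of 2.18 ± 0.47, Klrg1 of 1.77, Ctla4 of 1.55 and Icos, a costimulatory receptor gene, of 1.32. Myc, a growth transcription factor, was weaker at 72 h by 1.42 ± 0.24, Bcl2, a survival gene, by 0.96 ± 0.15 and Foxp3 by 0.55 ± 0.13 (adjusted p 0.0041). Larger lower differences included the macrophage gene Mertk, at -5.73 ± 0.73 (adjusted p 2.9e-05). For Il2ra the difference was -0.0584 ± 0.16 (adjusted p 0.84) and for Tcf7 0.23 (0.34), neither called. Of the genes called after FP at both 1.5 h and 16 h, 835 of 848 moved the same way, with 548 shared higher where 108 would be met by chance and 287 lower against 56 (p 2.5e-161). Between 16 h and 72 h it was 2437 of 2557, and between 72 h and 168 h 192 of 195, with 169 shared lower against 21.9 (p 9.2e-146). Among these shared lower genes were 26 of a list of 36 macrophage genes weighed further below, all 36 of which were called lower at 72 h. Whether their fall lies in the Tregs stays open.

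IL-2 added in vitro for 1.5 h (n = 3 and 3) tested the response outside the animal. Kcnj15 rose by 4.32 ± 0.13, Gpr83, a Treg-enriched receptor gene, by 3.23 ± 0.041 (34.9 ± 0.672 to 328 ± 8.54 CPM), Socs1 by 2.82 ± 0.05, Socs2 by 2.03 ± 0.068, Cish by 1.72 ± 0.036 and Foxp3 by 1.37 ± 0.04 (368 ± 17.6 to 952 ± 32.7 CPM). Bcl6 fell by 3.25 ± 0.041 (313 ± 6.94 to 33.0 ± 1.02 CPM), the cytokine receptor gene Il21r by 1.08 and Tcf7 by 0.63. edgeR called 2318 genes (1231 higher, 1087 lower). STAT5 targets were higher in 19 of 26 and lower in 5 (19 and 6 adjusted over the list alone, adjusted camera p 8.1e-18), Treg core genes higher in 13 of 18 and lower in 2 (p 2.2e-15), ribosome biogenesis genes higher in 19 of 34 (21 adjusted over the list alone, p 1.4e-11) and interferon-stimulated genes in 10 of 31 (12 adjusted over the list alone, p 5e-07). Treg core and interferon-stimulated genes kept the call with an estimated correlation (adjusted p 0.043 each), and STAT5 targets (0.077) and ribosome biogenesis (0.19) did not. Higher genes shared with IL-2 in the animal at 1.5 h numbered 476 against 105 by chance (p 6.2e-212), and lower genes 339 against 63.4 (p 5.7e-170).

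Response in the dish and in the animal differed for 848 genes by the interaction, 338 with a higher and 510 with a lower log2 change in vitro, whatever the direction of the response. The test fitted a common spread to both tables, although the biological variation was 4.48% in vitro and 16.3% in the animal. It can thus understate the spread in the animal, so its SEs and p-values can be too small. Lif had a log2 change of -0.249 in vitro against 3.96 in the animal (difference -4.21 ± 0.17, adjusted p 1.3e-09). Its level in vitro was already 51.4 to 52.2 CPM without IL-2, far above the PBS level in the animal. Hbegf, Kcnk5 and Il2ra rose less in vitro, by 2.95 ± 0.25, 2.70 ± 0.18 and 0.95 ± 0.10, and Pim1, a kinase gene of STAT5 output, had a change of -0.305 in vitro against 0.967 in the animal (difference -1.27 ± 0.16). Levels without IL-2 differed too. Pim1 stood at 851 ± 2.69 CPM in vitro against 217 ± 43 in the animal, and Ccr7 at 1560 against 193. Il2ra (390 against 597) and Tcf7 (282 against 478) were lower in vitro. Differences in change can thus reflect the starting level as well as the response. The falls of Tcf7 and Il7r were smaller in vitro, -0.649 against -1.51 and -0.52 against -1.62. Cd200, a ligand of an inhibitory receptor, the death receptor gene Fas and Gpr83 had changes higher in vitro by 1.95 ± 0.12, 1.87 ± 0.14 and 1.83 ± 0.18. Cish (-0.21 ± 0.15, adjusted p 0.47) and Socs2 (-0.20, 0.54) did not differ by the test. The count was 552, 564 and 513 without in vitro IL-2 libraries 1, 2 and 3, and 556 and 531 without in vitro PBS libraries 2 and 3.

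High-dose IL-2 (n = 3 and 3) was asked to show whether more IL-2 gives the late state of FP. edgeR called 0 genes, with 2743 at an unadjusted p below 0.05, and DESeq2 called 549 (410 higher, 139 lower). Gzmb was at 157 ± 75.2 against 2.64 ± 0.769 CPM (log2 change 5.88 ± 0.46, adjusted p 0.011), the mitotic kinase gene Plk1 was higher by 2.93 ± 0.24 (0.011), Birc5 by 4.27 ± 0.42 (0.012), Il1rl1 by 2.1 ± 0.20 (0.011) and the antiviral gene Rsad2 by 2.57 ± 0.28 (0.012). Il2ra differed by -0.0991 (95% interval -0.442 to 0.244), Cish by -1.22 ± 0.25 and the ribosome biogenesis gene Rrp12 by -1.36 ± 0.19, all uncalled. No list member was past the test over all genes, while 48 of 52 histone genes were higher adjusted over the list alone (median 3.3, adjusted camera p 1.3e-58), as were 30 of 42 cell cycle genes (p 2.1e-35), 17 of 31 interferon-stimulated genes (p 3e-23) and 8 effector Treg genes (p 1.8e-11), with 13 ribosome biogenesis genes lower (p 2.2e-14). None kept its call with an estimated correlation (adjusted p 0.21 to 0.84). By DESeq2 387 of the higher genes were shared with FP at 72 h against 87.8 by chance (p 1.9e-233), and 93 of the lower against 20.3 (p 7.4e-45). The edgeR count was 54 without PBS library 2, 1 without IL-2 library 1, 27 with RLE factors and 294 with the TEC share as a covariate, which was added after seeing the data.

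**Figure D3:**
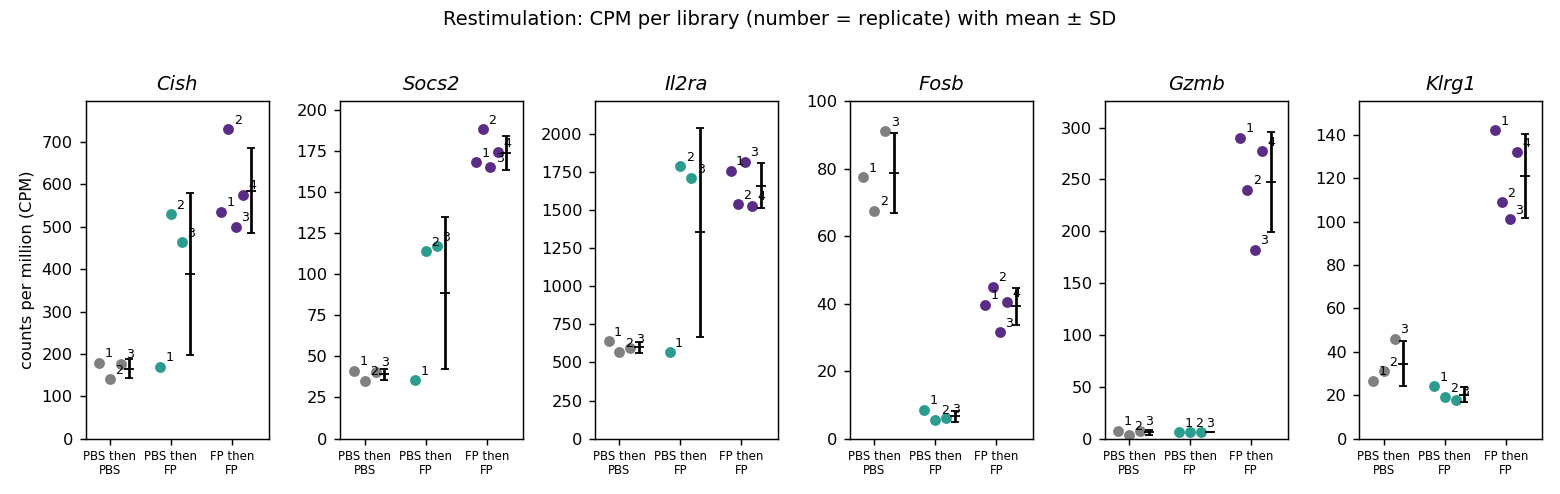
CPM of early and late genes in each library of the restimulation table, with mean ± SD per group.

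A single FP injection in the restimulation table (n = 3 and 3) served as the first-contact reference. edgeR called 2 genes, the immediate early genes Fosb and Fos, subunits of the AP-1 transcription factor. Fosb fell by 3.55 ± 0.21 (78.7 ± 11.8 to 6.70 ± 1.63 CPM, adjusted p 0.00018) and Fos by 2.00 ± 0.15 (75.6 ± 10.0 to 18.8 ± 0.567 CPM, 0.0010). Cish was at 170, 530 and 464 CPM in the 3 single-injection libraries against 179, 140 and 177 after PBS, and Il2ra at 566, 1790 and 1710 CPM, so library 1 lacked the early response that the other libraries show. Yet its Fos (18.9 CPM) was as low as theirs (18.2 and 19.3). Its Fosb (8.56) was somewhat above theirs (5.54 and 5.99) and far below PBS (67.6 to 91.1). The fall of Fos and Fosb was thus seen with and without the early response. Neither gene was called lower by edgeR after FP in the 1.5 h table, so the fall is not shown to be an effect of FP. Il2ra (1.17 ± 0.34), Socs2 (1.18 ± 0.35) and Myc (1.47 ± 0.35, adjusted p 0.13) were not called. DESeq2 called 143 genes (25 higher, 118 lower), the TEC share as a covariate, added after seeing the data, gave 160, and 1608 had an unadjusted p below 0.05. Histone genes had a median of -0.96 (adjusted camera p 5e-37), cell cycle genes of -0.60 (7.1e-15), STAT5 targets of 0.32 (3.2e-05) and conventional helper T cell genes of -0.30 (0.034), with no member past the test, and immediate early genes had 2 of 27 lower (2 higher and 3 lower adjusted over the list alone, p 0.00016). With an estimated correlation all had an adjusted p of 0.40 to 0.92. Without single-injection library 1 the count was 31 (27 higher, 4 lower), and without library 2 or 3 it was 1.

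After a second FP injection (n = 4) Gzmb was higher than after PBS (n = 3) by 5.36 ± 0.35, at 247 ± 48.3 against 6.01 ± 2.59 CPM (adjusted p 0.00041), Klrg1 by 1.81 ± 0.22 (34.6 ± 10.2 to 121 ± 19.1 CPM), Il1rl1 by 1.89 ± 0.20, Pim1 by 1.52 ± 0.21 and Il2rb, the beta chain gene of the IL-2 receptor, by 1.22. Il2ra (1.47 ± 0.33) and Socs2 (2.15 ± 0.35, adjusted p 0.011) were higher without being called. Without single-injection library 1 in the shared spread, a fit added after seeing the data, both were called (1.47 ± 0.12, adjusted p 9e-04, and 2.15 ± 0.11, 0.00011) among 169 genes. Cdc6 fell by 1.65. No group received FP and then PBS, so what the first injection left cannot be told apart from what the second added. In the 168 h table, after 1 FP injection, Klrg1 stood at 115 ± 47.1 CPM, Il1rl1 at 138 ± 30.7 and Il10 at 28.8 ± 7.22. After repeated FP they stood at 121 ± 19.1, 141 ± 33.3 and 36.4 ± 7.44, whereas Gzmb was at 87.1 ± 72.1 at 168 h and 247 ± 48.3 here. Gzmb at 168 h was 195 CPM in FP library 1 and 46.5 to 56.8 in the others. The labels do not give the time between the injections, and the levels come from separate tables. They therefore do not show what the first injection had left. Against the single injection (n = 3) Gzmb was higher by 5.33 ± 0.35, Il10 by 2.89 ± 0.42 (4.87 ± 3.03 to 36.4 ± 7.44 CPM), Klrg1 by 2.58 ± 0.22, Fosb by 2.55 ± 0.20, Fos by 2.27 ± 0.15 and the chemokine gene Ccl5 by 2.43 ± 0.29. For Fosb and Fos the difference starts from the low level of all single-injection libraries, library 1 among them. Il2ra differed by 0.297 (95% interval -0.321 to 0.915, and -0.0712 without single-injection library 1) and Myc by 0.129 (-0.495 to 0.752). Myc was at 127 CPM in single-injection library 1 and at 377 and 356 in libraries 2 and 3, against 313 ± 44.4 after repeated FP. Its positive sign thus rests on library 1. edgeR called 113 genes against PBS (67 higher, 46 lower) and 105 against the single injection (79 and 26), and DESeq2 736 and 547. A fit of only the compared groups gave 59 and 43, and the TEC share as a covariate, added after seeing the data, 683 and 488. With replicate numbers as a block, which did not pair these libraries, all 3 comparisons of the table had 0, and for the count against PBS chance was not excluded, another split of the libraries calling 1473. Against PBS the count was 13, 37 and 5 without FP libraries 1, 2 and 4, and 4, 3 and 23 without PBS libraries 1, 2 and 3. Against the single injection it was 21, 39 and 17 without FP libraries 1, 2 and 4, and 19, 4 and 8 without single-injection libraries 1, 2 and 3.

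STAT5 targets were higher after repeated FP than after PBS in 4 of 26 (16 higher and 1 lower adjusted over the list alone, median 1.1, adjusted camera p 6.6e-14), and effector Treg genes in 3 of 29 (12 higher and 1 lower adjusted over the list alone, p 2.1e-10). Cell cycle genes had 1 lower (5 adjusted over the list alone, median -0.66, p 4.3e-10) and BCL2 family genes a median of 0.32 with no member past (1 higher adjusted over the list alone, p 0.022). Mki67 was at 12.7 and 23 CPM in FP libraries 2 and 4, of low TEC share (0.26% and 0.322%), and at 62.2 and 63.4 in FP libraries 1 and 3. FP library 1, however, had a TEC share of 0.414%, nearer to these than to the 0.795% of FP library 3. After PBS Mki67 was at 24.6 in library 3, also of low TEC share, and at 85.7 and 97.9 in libraries 1 and 2. Mki67 thus did not follow the TEC share in every library. Still, the cell cycle shift cannot be told apart from how libraries of low TEC share fall on the groups. Against the single injection effector Treg genes were higher in 8 (15 adjusted over the list alone, p 3.7e-15), immediate early genes in 2 of 27 (12 higher and 2 lower adjusted over the list alone, p 1.8e-08) and STAT5 targets in 2 (7 adjusted over the list alone, p 1.2e-07, and 9.2e-05 without single-injection library 1, whose early genes were at the PBS level), and myeloid markers were lower in 1 (9 adjusted over the list alone, p 3.7e-07). With an estimated correlation none kept its call, at an adjusted p of 0.21 to 0.53 against PBS and 0.44 to 0.70 against the single injection.

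**Figure D4:**
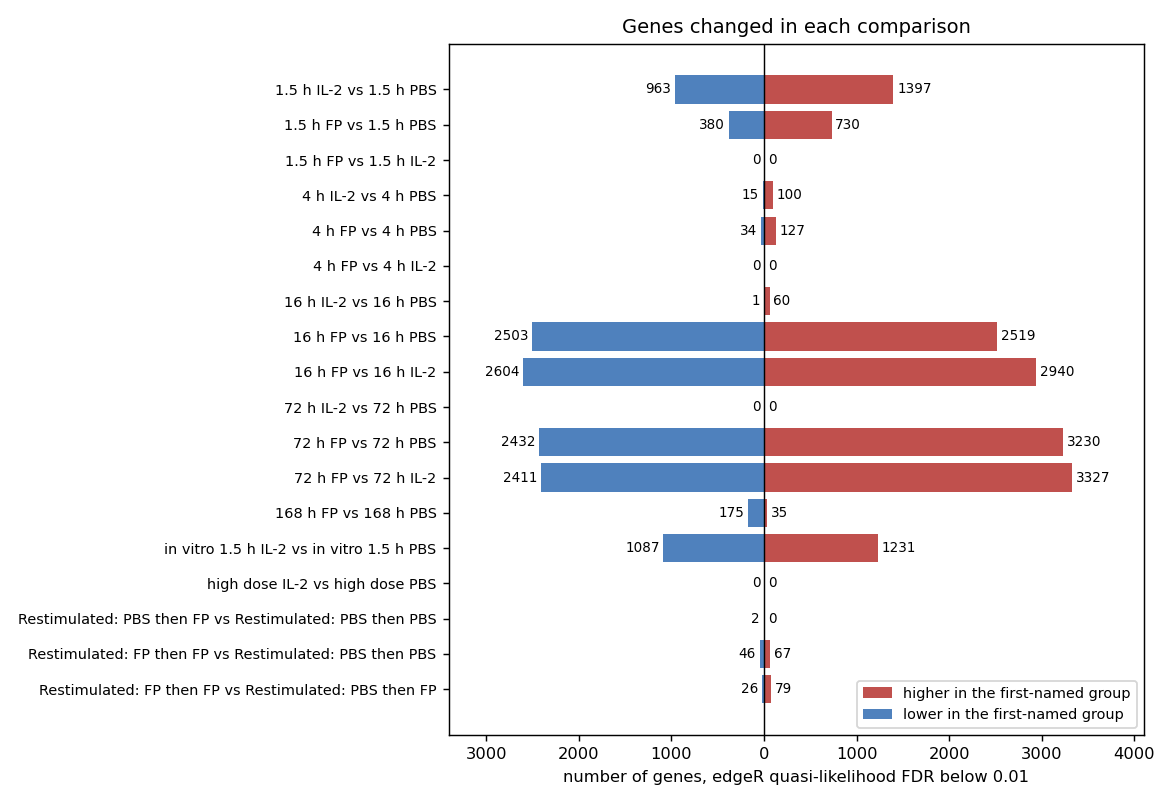
Genes called higher and lower by edgeR in each comparison.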

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

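The values in this paragraph were picked by rules set in advance, and the reading of the unassigned library was chosen after seeing its values. Among the FP libraries at 1.5 h, library 4 had 1840 CPM of Il2ra (others 2130 to 2140) and 1020 of Ikzf2, a transcription factor gene of Tregs (1210 to 1230), and PBS library 4 had 270 of the homing receptor gene Ccr7 (166 to 169). At 16 h, FP library 4 had 98.4 CPM of Gzmb (74.6 to 78.5) and 43.8 of Il7r (64.1 to 65.8), FP library 1 had 147 of Ccr7 (123 to 127) and 254 of S1pr1 (225 to 229), IL-2 library 4 had 413 of Tcf7 (450 to 457) and a total of 13.9 M (16 to 16.3), and PBS library 3 had 7.86 of Gzmb (2.57 to 3.24). FP library 4 at 72 h had 579 CPM of Gzmb (860 to 908), and FP library 1 at 168 h had 195 of Gzmb (46.5 to 56.8) and 109 of Mki67 (56.7 to 58.7). After repeated FP, library 2 had 379 CPM of Myc (285 to 301) and library 1 had 109 of Icos (74 to 79.3). The rule picked 16 values in 250 checks of the spread within a group, where about 1 in 20 is met by chance. An unassigned 4 h library, number 2, had 588 CPM of Cish (146 to 239 in the PBS libraries), 130 of Socs2 (18.5 to 36.8) and 2160 of Il2ra (440 to 792).

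Every comparison was weighed with a test written before the results, the split of the same libraries into groups of the same sizes, and setting other splits beside the TEC share of the libraries was chosen after seeing them. At 1.5 h, 1 of 35 splits, the real one, had as many genes for IL-2 against PBS (2360, highest other 0) and for FP against PBS (1110, 0). For FP against IL-2 the real count was 0, which all 35 splits must reach, so the test says nothing (highest other 211). At 4 h, IL-2 against PBS stood alone at 115 (1 of 35, highest other 0), while FP against PBS (161, 1 of 10, highest other 0) had too few splits to tell. FP against IL-2 at 4 h also had a real 0, reached by all 35, and the highest other had 4005, which points to structure in the libraries that the groups do not carry. At 16 h the real split stood alone at 61, 5022 and 5544 for IL-2 against PBS, FP against PBS and FP against IL-2 (1 of 35 each, highest other 0). At 72 h, FP against PBS had 5662 (1 of 35, highest other 1521) and FP against IL-2 had 5738 (1 of 35, 1740), and IL-2 against PBS (0, 10 of 10, highest other 0) had too few splits. FP at 168 h had 210 (1 of 35, highest other 0). In vitro IL-2 (2318, 1 of 10, 0), high-dose IL-2 (0, 10 of 10, 0) and single FP in restimulation (2, 1 of 10, 0) had too few splits as well. Repeated FP against PBS had 113, and 2 of 35 splits reached it, the other calling 1473, so chance is not excluded and another structure, which follows the TEC share of the libraries, calls more genes than the treatment. Repeated against single FP had 105 (1 of 35, highest other 0). The interactions had 2581 (1 of 40, highest other 395) for FP at 72 h and 1.5 h, and 848 (1 of 40, 489) for IL-2 in vitro and in the animal.

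In the restimulation table, tests on single-injection library 1 were chosen after seeing its values, except the test for a PBS library with a wrong label, whose gene limits were still set later, with Fos and Fosb of this library already seen. Library 1 lacks the rise of Cish, Socs2 and Il2ra that libraries 2 and 3 show. Against a swap within the table, 0 of 3 PBS libraries had these 3 genes past the midpoint between PBS and libraries 2 and 3. Against a PBS library with a wrong label, its median position from PBS (0) to libraries 2 and 3 (1) was 0.77 over 112 genes not called at 1.5 h (quartiles 0.53 to 0.97), and 0.53 to 0.80 when each PBS library marked the PBS end in turn. Over the 728 genes called higher by FP at 1.5 h its position was 0.085, so an injection that did not reach the spleen, or a label from outside the table, stays open.

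Tests on the low count at 4 h were all chosen after seeing it. FP changed 161 genes at 4 h against 1110 at 1.5 h. Smaller effects are argued against by a median ratio of 4 h to 1.5 h log2 changes of 1.2 over 1109 genes, 98.1% of them with the same sign, and lower depth by a lowest total of 14.5 M among the grouped libraries at 4 h, above the 12.2 M at 1.5 h. With the tag in the column names as a factor the count rose to 1684, as a batch axis would give. What the tag stands for stays open.

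Tests on macrophage genes were all chosen after seeing them fall. Of 19 macrophage genes not named before, 94.7% had a log2 change below -1 after FP at 72 h, as fewer macrophages, or less of their RNA, among the sorted cells would give. Over the whole list the median was -0.487 at 16 h (6 genes called lower), -3.57 at 72 h (36), -3.42 at 168 h (26) and -0.955 after repeated FP against PBS (0). Scaling, which moves all genes of a library alike, is argued against by the macrophage median lying -3.52 from that of all other genes (quartiles -4.54 to -2.83, others -0.463 to 0.368), and an equal loss of every other cell type by the macrophage median lying -2.79 from the lower of the B cell and erythroid medians. Sorting on the Foxp3 reporter should exclude macrophages, and whether Tregs themselves changed these genes stays open.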

How the results depend on the processing

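DESeq2 in place of edgeR called 1700 genes for FP at 1.5 h and 1 for FP against IL-2, 790, 1100 and 4 for IL-2, FP and FP against IL-2 at 4 h, 137 for IL-2 at 16 h, 520 at 168 h, 549 at high dose, and 143, 736 and 547 for single FP, repeated FP and repeated against single FP in restimulation. RLE factors gave 27 at high dose. A fit of only the compared groups gave 27 and 0 for IL-2 and FP at 4 h, 7 for IL-2 at 16 h, and 59 and 43 for repeated FP against PBS and single FP. With the lane as a covariate 4 h had 47 and 0. Added after seeing the data, the column tag gave 1252, 1684 and 1 at 4 h, and the 2 libraries of contradicting labels grouped by title gave 379, 596 and 0. The TEC share, also added, gave 1829, 2618 and 1 at 4 h, 294 at high dose, and 160, 683 and 488 in restimulation. Leaving out each library gave 689 to 1099 for FP at 1.5 h, 1 to 90 and 10 to 89 for IL-2 and FP at 4 h, 19 to 72 for IL-2 at 16 h, 3549 to 6620 and 3727 to 6704 for FP at 72 h against PBS and IL-2, 128 to 209 at 168 h, 0 to 54 at high dose, 1 to 31, 3 to 137 and 4 to 131 in restimulation, and 513 to 1126 for the in vitro interaction. The cause was not tested. List calls fell from 200 to 13 with an estimated correlation. Of 7884 values of called genes 738 lost the call and 0 changed sign.

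A replicate block gave 509 genes for IL-2 and 994 for FP at 4 h, and 0 for each of the 3 restimulation comparisons. At 4 h the replicate numbers are not shown to be pairs. With this replicate block, glycolysis genes gained a call at 4 h (adjusted p 0.00024 after IL-2, 0.0075 after FP), as did oxidative phosphorylation genes after IL-2 (0.00026) and, after FP, interferon-stimulated genes (0.029) and, lower, chromatin regulators (0.045). At 72 h of IL-2, where no gene was called, oxidative phosphorylation (0.00018), histone (0.0036), immediate early (0.0054) and amino acid supply genes (0.014), myeloid (0.013) and B cell markers (0.034) gained a lower call and chemokine receptor and homing genes a higher one (0.045). Of 8470 values of uncalled genes under the naming rule, 393 gained a call and 182 changed sign. Of the 673 values of uncalled genes named here, 70 gained a call and 10 changed sign. Socs2, 1.5h-FP vs 1.5h-IL2, ran from -0.146 to 0.0077 as each library was left out, above 0 without IL-2 library 3. Gzmb, 4h-FP vs 4h-IL2, was -0.101 with the replicate block, -0.146 with the tag, -0.0493 with the TEC share, -0.0287 with the libraries grouped by title, and -0.306 (without FP library 1) to 0.433 as libraries were left out. Mki67, 72h-IL2 vs 72h-PBS, ran from -0.161 to 0.124, with 0.124 without IL-2 library 3 and 0.104 without PBS library 1. Il2ra, 168h-FP vs 168h-PBS, ran from -0.126 to 0.00372 (without FP library 3), and Il2ra, Restimulate-1.5h-FP vs Restimulate-1.5h-single, from -0.0712 (without single-injection library 1) to 0.554. Depth of 12.2 to 15.3 M at 1.5 h limits genes of few reads.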

Other observations

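Bcl6 fell in vitro by 3.25 ± 0.041 within 1.5 h of IL-2 (n = 3 and 3) and after FP by 2.2 ± 0.12 at 16 h (n = 4 and 4), while Tcf7 fell by 0.63 and 1.07. Klrg1 first fell after FP, by 0.76 ± 0.14 at 16 h, and then rose by 1.51 at 72 h and by 2.29 ± 0.32 at 168 h (n = 4 and 3), and Cd83, an activation marker, fell by 1.25 at 16 h and 2.51 at 72 h. Ccr6, a receptor of T cells that home to mucosa, fell by 1.50 at 72 h and 1.27 at 168 h. Fos and Fosb were lower in the single-injection libraries of the restimulation table, also in library 1 (18.9 and 8.56 CPM), which lacked the early response and whose treatment stays open. In vitro IL-2 lowered Fos by 0.51. After repeated FP (n = 4), Fos stood at 90.6 ± 13.7 CPM against 75.6 ± 10 after PBS (n = 3), and Fosb at 39.2 ± 5.63 against 78.7 ± 11.8.

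In the 4 h table the labels of 2 libraries contradict each other. Title, treatment label and column name agree, on PBS for library 1 and on FP for library 2, and the injected molecule names the reverse. Library 1 had 166 CPM of Cish, 32.5 of Socs2, 575 of Il2ra, 82.5 of Myc, 5.85 of Lif, 36.7 of Myb and 2.29 of Gzmb. Library 2 had 588 CPM of Cish, 130 of Socs2, 2160 of Il2ra, 260 of Myc, 71.8 of Lif, 296 of Myb and 11.3 of Gzmb. None of these 7 genes was above the range of the PBS libraries in library 1, and all were above it in library 2, as the titles would have it. No group was taken from values, and the original sample sheet would settle both.

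Lif rose by 3.96 ± 0.23 in the animal and had a log2 change of -0.249 in vitro, while Cish and Socs2 did not differ by the interaction. In vitro, however, PBS libraries 1, 2 and 3 already held 52.2, 51.4 and 51.7 CPM of Lif, far above the PBS level in the animal. The missing rise thus cannot show that a signal is absent from the culture. Whether Lif needs a signal found only in the animal stays open. Which cells were cultured is not in the labels. Tregs cultured with IL-2 with and without spleen cells would test this. The late state after FP, with Gzmb at 813 ± 158 CPM at 72 h, could come from the length of the IL-2 signal or from its strength. IL-2 left 0 called genes at 72 h (0 with DESeq2), while high-dose IL-2, of a dose and time not in the labels, had 0 by edgeR and 549 by DESeq2, and 387 of its higher genes were shared with FP at 72 h. Repeated small doses of IL-2 over 72 h would separate length from dose. Fewer macrophages in the sorted samples could explain the loss of Slc40a1 and Cd163 (94.7% of remaining macrophage genes below -1). Counting red pulp macrophages in tissue sections after FP would test their number in the spleen, though not the make-up of the sorted samples.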
